A study of Mus musculus with 10 samples.

How the data were processed

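Poly(A) RNA from sorted splenic B cells of 10 mice was read as single-end 50 nt reads, per the labels. Cells were stained for B220 and the reporter, sorted with exclusion of dead cells by 7AAD and lysed in TRIzol. The authors deposited raw read counts per gene, 1 column for each library, made with featureCounts after FastQC on the genome GRCm39. Aligner, annotation release, strand setting and tool versions are not given in the sources used here. All values were whole numbers, and every column was matched to its sample with 0 left over. The pBIC10 libraries belong to this series, and the pBIC and YC libraries were re-analysed by the authors from an earlier one.

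Groups were pBIC10 (n = 3), pBIC (n = 3) and YC (n = 4), compared in 3 contrasts. Genes were kept by filterByExpr of edgeR 4.0.16 (R 4.3.3), which left 17718 of 46316. Counts were scaled by TMM and fitted for all 10 libraries with 1 coefficient per group (quasi-likelihood, robust). A gene was called at an adjusted p under 0.05 (two-sided F test, Benjamini-Hochberg within each comparison). Every adjusted p of a gene is from edgeR unless another tool is named. The SE of a log2 fold change is its size divided by the square root of F, an approximation. The common dispersion was 0.0835 (biological coefficient of variation 0.289), with 7 residual and a median of 6.15 prior degrees of freedom. CPM of genes are TMM-scaled, and those of variable segments and sex-linked genes use all counts of a library.

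Gene lists written before the data were examined (38, of which 37 had at least 5 tested members) were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01. Adjusted p-values are over the lists of a comparison. Camera compares list genes with all others, which assumes that most other genes do not share the shift. The contrasts, tests, lists, alternatives and naming rule were likewise chosen before the data were examined. Genes were named by rule. The 4 targeted genes were always named. Of called genes with at least 5 CPM in the higher group and no overlap between libraries, the 10 largest changes in each direction qualified, without immunoglobulin, T cell receptor, sex-specific, mitochondrial and predicted genes. From lists called, or with 3 or more called members, up to 4 members in each direction with the smallest adjusted p qualified. The text gives a part of the genes that qualified, picked after their values were seen.

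A group with 0 counts was given a bound of 3 counts over the group. Groups with 1 to 3 counts were given a ratio with its exact 95% counting interval. Principal components used log2 CPM of the 500 most variable genes. Shares of variable segments are of all counts of that kind of segment in a library, with exact 95% binomial intervals. Intervals and bounds cover counting error only. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).

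The pipeline was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold in each comparison. Of the genes changed 2-fold it found 11 in pBIC10 against pBIC, 29 in pBIC against YC and 33 in pBIC10 against YC. Of those changed 4-fold it found 55, 70 and 76. In pBIC10 against pBIC, 50 of 62 genes changed 4-fold were found at 5 CPM or more and 5 of 38 below. Far fewer genes were changed than were called in the real data, which makes the adjusted p harder to pass. These shares therefore do not give the power in the real data. Unchanged genes made up 6 of 72, 9 of 108 and 8 of 117 calls, and 0 had the wrong direction. A list planted in each comparison was found, with 0 other lists called. The simulated genes were drawn independently of each other, so this check cannot test the preset correlation used by camera. In the real data the estimated correlation was 0.385 for interferon gamma response genes, 0.356 for MHC class I presentation genes and 0.567 for ribosomal protein genes.

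Alternatives were other scalings, DESeq2 1.42.0, limma-voom, other filters, a fit of 2 groups, sex as a covariate, females alone, immunoglobulin and T cell receptor genes left out, stricter thresholds and leaving out each library in turn. For lists an estimated correlation and fry were run as well. Ranges over alternatives given for list calls leave these out. Summing each lymphoma group to 1 library was added after seeing the data. Mitochondrial protein-coding genes were not analysed here. Genes were matched by symbol to a reference of an earlier genome build for GC content, length and chromosome, and no positions are given.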

Results

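RNA was sequenced from sorted B cells of the spleens of 10 mice in 3 groups. The pBIC group (3 libraries, all from females) and the pBIC10 group (3 libraries, from 2 females and 1 male) come from a mouse model of activated B cell-like diffuse large B cell lymphoma. In that model Cre made from the Cγ1 locus, which is active in germinal centre B cells, deletes the genes of p53 and Blimp1 and turns on an active form of the kinase IKK2. The pBIC10 mice also carry a floxed Il10 gene, so their lymphoma cells are deficient in the cytokine IL-10. The YC group (4 libraries, from 3 females and 1 male) holds reporter-positive germinal centre B cells without lymphoma, taken 10 days after the second of 2 immunisations with sheep red blood cells. Some label fields of the YC libraries repeat the wording of the lymphoma libraries (GFP, moribund mice), and the series description was followed for them.

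The count table held 46316 genes. The pBIC10 libraries had 17.1, 17.1 and 18.6 M counts, the pBIC libraries 17.8, 19.13 and 18.6 M, and the YC libraries 13.5, 12.59, 14.3 and 13.8 M. A count of 0 in a single library allowed a level of up to 0.157 to 0.238 CPM (counts per M, set by 3 counts). Of all genes, 17718 had enough counts to be tested. Levels are given as mean ± SD in CPM (n = 3 for pBIC10 and pBIC, n = 4 for YC), and log2 fold changes as estimate ± SE. In every gene given as changed in this section, all libraries of 1 group lay above all libraries of the other in that comparison, except Lgmn and Il10 in pBIC10 against YC. Directions against YC among the flagged results were not held to this.

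The 3 groups separated fully. The first principal component of the 500 most variable genes held 66.5% of their variance and the second 28.0%. The largest distance between libraries of 1 group was 18.3 units on these components, and the smallest between libraries of different groups was 85.0. Pearson correlations across genes lay between 0.960 and 0.984 within groups and between 0.813 and 0.902 across them, and genes are not independent replicates. Immunoglobulin genes held 1.13% of counts in pBIC10, 0.966% in pBIC and 4.40% in YC.

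**Figure D1:**
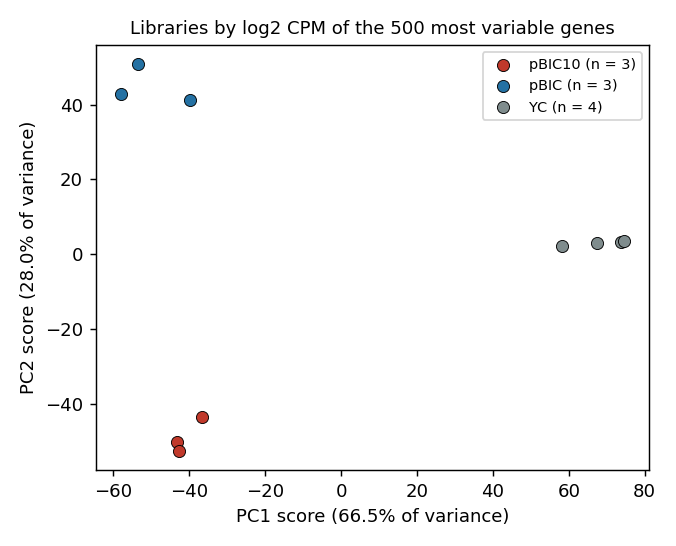
Scores of the 10 libraries on the first component (66.5% of variance, x axis) and the second (28.0%, y axis) of log2 CPM of the 500 most variable genes, 1 point per library and coloured by group. Libraries of a group lie within 18.3 units of each other and groups at least 85.0 units apart.

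The 4 genes that the alleles act on were read in every library. Trp53, which encodes the tumour suppressor p53, stood at 198, 194, 198 and 176 CPM in the YC libraries, at 23.2, 18.3 and 53.3 CPM in pBIC and at 47.4, 49.7 and 36.6 CPM in pBIC10. Prdm1, which encodes the plasma cell regulator Blimp1, stood at 30.1, 39.6, 16.8 and 28.3 CPM in YC, at 5.63, 16.3 and 8.03 CPM in pBIC and at 0.649, 0.351 and 1.59 CPM in pBIC10. Ikbkb, which encodes IKK2, stood at 126, 166, 144 and 129 CPM in YC, at 335, 223 and 298 CPM in pBIC and at 422, 414 and 335 CPM in pBIC10. Il10, which encodes IL-10, stood at 4.23, 7.45, 7.14 and 9.98 CPM in YC, at 19.4, 6.84 and 8.78 CPM in pBIC and at 2.71, 1.99 and 4.77 CPM in pBIC10. Reads were counted over whole genes, so transcripts of a deleted allele that keep other exons are included.

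**Figure D2:**
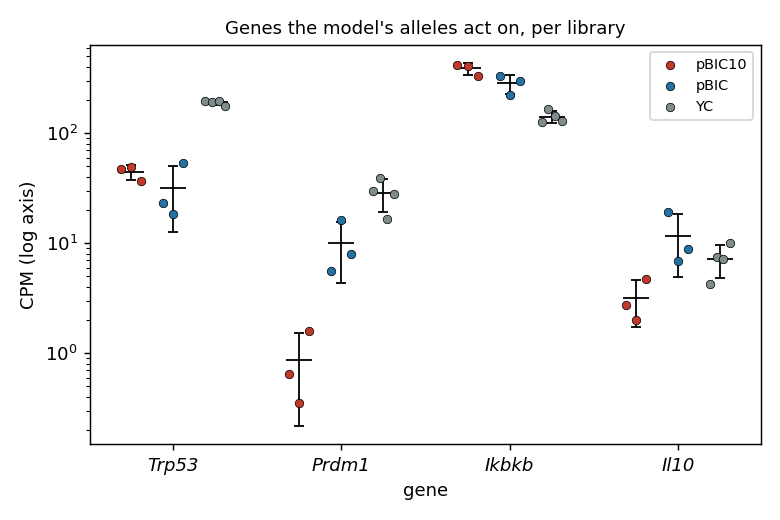
Levels of Trp53, Prdm1, Ikbkb and Il10 in each library (y axis, CPM on a log scale), 1 point per library in the 3 groups, with the mean as a dash and the SD as a bar. Il10 lies between 1.99 and 4.77 CPM in pBIC10 and between 6.84 and 19.4 CPM in pBIC.

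Immunoglobulin variable segments, which differ between B cell clones, were shared within each lymphoma group. Ighv7-3, a heavy chain segment, held 67.4 to 70.5% of heavy chain variable counts in the 3 pBIC10 libraries, up to 0.0759% in pBIC and 0.119 to 1.73% in YC. Ighv8-11 led in the 3 pBIC libraries with 51.6 to 59.1%, against up to 0.0345% in pBIC10 and 0.279 to 1.04% in YC. Among light chain segments, Iglv2 held 80.7 to 85.4% of lambda counts in pBIC10 and 10.5 to 13.9% in YC. Igkv6-17 held 72.7 to 77.8% of kappa counts in pBIC and 0.957 to 2.51% in YC. In YC the leading lambda segment was Iglv1 in every library, with 75.3 to 81.2%. Each YC library had a different leading heavy chain segment, with 3.73 to 10.9%. The adjusted p-values below treat the libraries of a group as independent, and they measure the spread among libraries that share these segments.

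**Figure D3:**
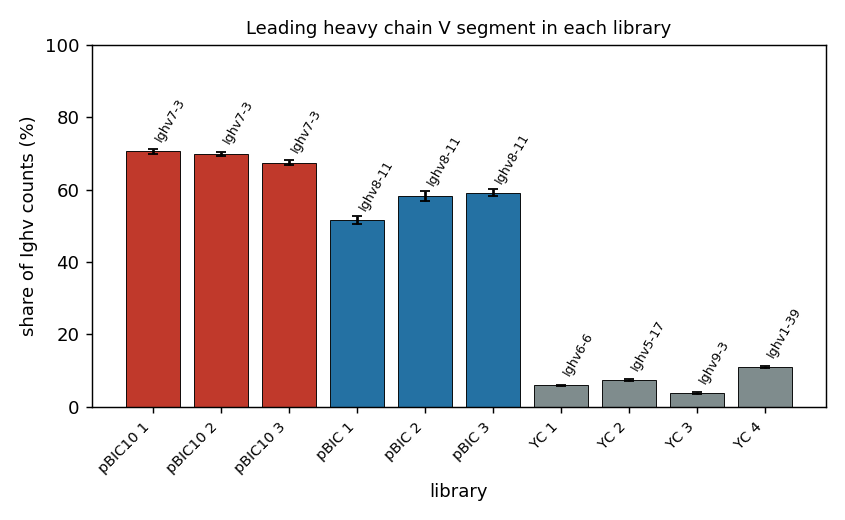
Share of heavy chain variable counts held by the leading segment of each library (y axis, percent, from 0), 1 bar per library with its exact 95% binomial interval, which covers counting error only. The pBIC10 bars (Ighv7-3) and pBIC bars (Ighv8-11) lie at or above 51.6%, and the YC bars between 3.73 and 10.9%.

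The comparison of pBIC10 with pBIC addressed how lymphoma cells deficient in IL-10 differ from those that can make it. The libraries of each group share their variable segments. If each group is 1 clone, a difference between clones cannot be told apart from one due to IL-10. Genes that respond to interferon gamma, a cytokine of T and NK cells, were lower in pBIC10, as were genes that load peptides on MHC class I molecules for display to T cells (adjusted p = 0.541 for each list with an estimated correlation). Among those genes were Gbp4, Irf1 and Tap1. Targets of NF-kB, the pathway that IKK2 drives, were also lower on balance in pBIC10, although Ikbkb itself was not called changed (adjusted p = 0.541 with an estimated correlation). The heavy chain gene Ighm was higher in pBIC10 and Ighg3 higher in pBIC.

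Of 17718 genes, 5440 (30.7%) were called changed between pBIC10 and pBIC, 2766 higher and 2674 lower in pBIC10, and 3511 of them differed at least 2-fold. The libraries of the groups did not overlap in 41.8% of all genes, where chance gives 10%. All pBIC10 libraries belong to 1 series and all pBIC and YC libraries to an earlier one, so library batch and group cannot be told apart in both comparisons of pBIC10. Il10 fell with a log2 fold change of -1.88 ± 0.46 (adjusted p = 0.00809) and Prdm1 with -3.50 ± 0.55 (adjusted p = 5.63e-04). Trp53 was not called changed (0.50 ± 0.31, adjusted p = 0.255), though without pBIC replicate 3 it was called higher in pBIC10 (1.11, adjusted p = 0.00124, range over alternatives 0.00124 to 0.720). Ikbkb was not called either (0.45 ± 0.19, adjusted p = 0.0818), though it was without pBIC replicate 1 (0.60, adjusted p = 0.0320, range 0.0320 to 0.834).

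Of 29 tested interferon gamma response genes, 27 were lower and 1 higher in pBIC10, with a median log2 fold change of -2.36 (camera adjusted p = 5.43e-14, adjusted p = 0.541 with an estimated correlation), and 1 higher and 27 lower when adjusted over the list alone. Gbp8 and Gbp4, guanylate-binding proteins that interferon gamma induces against pathogens inside cells, fell most clearly. Gbp8 stood at 3.22 ± 1.14 CPM in pBIC10 and 62.1 ± 21.9 CPM in pBIC, log2 fold change -4.27 ± 0.37, adjusted p = 5.08e-06. Gbp4 stood at 15.1 ± 5.26 CPM in pBIC10 and 233 ± 94.4 CPM in pBIC, log2 fold change -3.95 ± 0.35, adjusted p = 8.73e-06. Irf1, a transcription factor that carries the interferon gamma signal on, stood at 81.6 ± 5.46 CPM in pBIC10 and 252 ± 25.2 CPM in pBIC, log2 fold change -1.63 ± 0.16, adjusted p = 1.33e-05. Icam1, an adhesion molecule for T cell contact, stood at 48.1 ± 0.941 CPM in pBIC10 and 155 ± 26.9 CPM in pBIC, log2 fold change -1.69 ± 0.18, adjusted p = 2.00e-05. The member that rose was Ifngr1, the ligand-binding chain of the receptor (0.58 ± 0.17, adjusted p = 0.0200), and this call was lost without pBIC10 replicate 3 (adjusted p = 0.0739) or pBIC replicate 3 (0.0579), with sex as a covariate (0.0530) and in females alone (0.109), with a range over alternatives of 0.0105 to 0.586. Type I interferon response genes had 13 of 35 lower and 5 higher (camera adjusted p = 0.0488, adjusted p = 0.722 with an estimated correlation), and 6 higher and 13 lower when adjusted over the list alone. That call was lost without pBIC replicate 1 (camera adjusted p = 0.476).

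Of 22 MHC class I presentation genes, 19 were lower and 0 higher in pBIC10, with a median of -1.17 (camera adjusted p = 1.63e-09, adjusted p = 0.541 with an estimated correlation), and 0 higher and 19 lower when adjusted over the list alone. Tapbp encodes tapasin, which holds class I molecules at the peptide transporter, and stood at 137 ± 13.9 CPM in pBIC10 and 358 ± 32.9 CPM in pBIC, log2 fold change -1.38 ± 0.15, adjusted p = 2.70e-05. Its relative Tapbpl, a peptide editor, changed by -1.84 ± 0.22, and Tap1, a subunit of the transporter, by -1.74 ± 0.21 (adjusted p of at most 5.31e-05). MHC class II presentation, which shows peptides to CD4 T cells, had 7 of 18 genes lower and 1 higher (camera adjusted p = 0.0374, adjusted p = 0.662 with an estimated correlation), and 2 higher and 7 lower when adjusted over the list alone. That call was lost without pBIC10 replicate 3 (adjusted p = 0.115) or pBIC replicate 1 (0.0912, 2 higher), with sex as a covariate (0.0505) and in females alone (0.115), with a range over alternatives of 0.0142 to 0.115. H2-Aa and H2-Eb1, which encode class II chains, changed by -1.73 ± 0.16 and -1.76 ± 0.18. Marchf1, a ubiquitin ligase that takes class II molecules off the surface, rose by 3.99 ± 0.58 (adjusted p of at most 3.81e-04 for the 3).

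**Figure D4:**
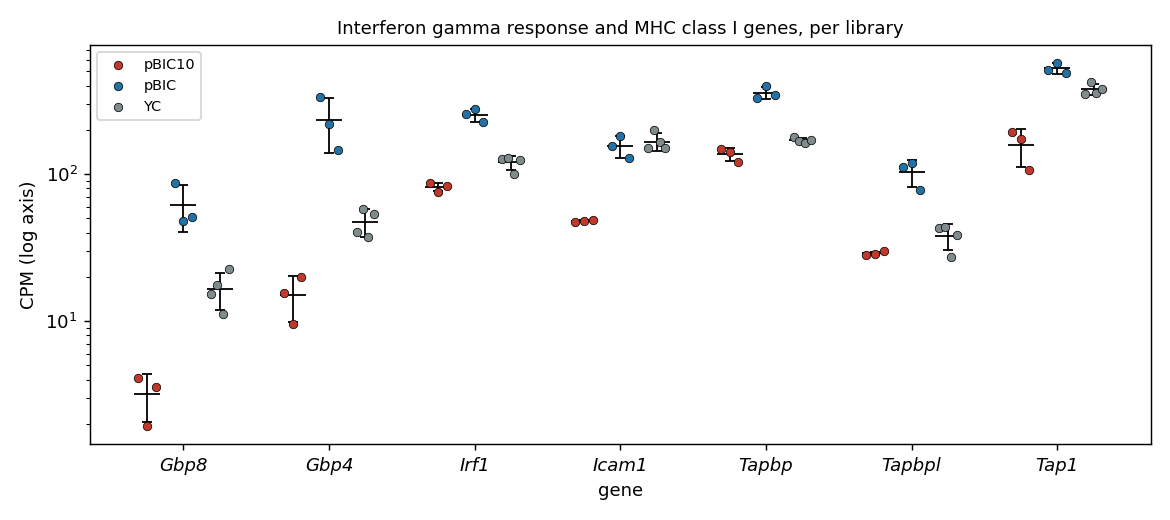
Levels of the interferon gamma response genes Gbp8, Gbp4, Irf1 and Icam1 and the class I presentation genes Tapbp, Tapbpl and Tap1 in each library (y axis, CPM on a log scale), 1 point per library in the 3 groups, with the mean as a dash and the SD as a bar. In each gene all pBIC10 libraries lie below all pBIC libraries.

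Of 43 NF-kB targets, 23 were lower and 2 higher in pBIC10 (camera adjusted p = 3.64e-06, adjusted p = 0.541 with an estimated correlation), and 2 higher and 24 lower when adjusted over the list alone. Cd83, a surface protein of activated B cells, stood at 21.1 ± 5.46 CPM in pBIC10 and 211 ± 65.8 CPM in pBIC, log2 fold change -3.32 ± 0.26, adjusted p = 2.66e-06. Gadd45b, a stress-response gene that NF-kB induces, was higher (2.46 ± 0.44, adjusted p = 0.00149). Birc3, an apoptosis inhibitor, was the other higher target (0.52 ± 0.18, adjusted p = 0.0455), and its call was lost without pBIC10 replicate 1 (adjusted p = 0.0812), 2 (0.140) or 3 (0.0651) or pBIC replicate 2 (0.169) or 3 (0.0822). It was also lost with sex as a covariate (0.0685) and in females alone (0.0894), with a range over alternatives of 0.00847 to 0.722. Of 26 genes of the IL-10 receptor and STAT3 pathway, 9 were lower and 4 higher (camera adjusted p = 0.0451, adjusted p = 0.662 with an estimated correlation), and 4 higher and 10 lower when adjusted over the list alone. This call was lost without pBIC10 replicate 3 (adjusted p = 0.132) or pBIC replicate 1 (0.102), with sex as a covariate (0.0902) and in females alone (0.133), with a range of 0.0266 to 0.133. Its members went both ways. Socs3, a feedback inhibitor that STAT3 induces, rose by 3.82 ± 0.50, and Fos, an immediate early factor, by 3.23 ± 0.71. Socs1, which limits interferon signalling, changed by -2.36 ± 0.25, and Batf, a factor of activated B cells, by -3.71 ± 0.37 (adjusted p of at most 0.00526 for the 4). The immediate early and heat shock genes, Fos among them, had 6 of 18 higher and 1 lower, with a median of 1.18, and were not called as a list (camera adjusted p = 0.0835, adjusted p = 0.662 with an estimated correlation). Adjusted over that list alone the counts were 6 and 1, and 4 were higher without any 1 of the pBIC10 libraries.

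The regulatory B cell genes, of which Il10 is a member, had 10 of 18 lower and 4 higher (camera adjusted p = 0.0279, adjusted p = 0.661 with an estimated correlation), and 4 higher and 11 lower when adjusted over the list alone. Without pBIC replicate 1 this call was lost (adjusted p = 0.0689, range over alternatives 0.00962 to 0.0689). Cd24a, a surface marker of immature and regulatory B cells, stood at 849.6 ± 41.3 CPM in pBIC10 and 86.8 ± 26.9 CPM in pBIC, log2 fold change 3.29 ± 0.23, adjusted p = 8.97e-07. Il12a, which encodes the p35 subunit of IL-12 and IL-35, rose by 5.82 ± 0.74, and Lag3, an inhibitory receptor that binds class II molecules, changed by -5.29 ± 0.57 (adjusted p of at most 1.50e-04). Of 23 cytokines and chemokines, 11 were lower and 3 higher (camera adjusted p = 0.00340, adjusted p = 0.661 with an estimated correlation), and 3 higher and 12 lower when adjusted over the list alone, among them Cxcl10, a chemokine that interferon gamma induces (-5.14 ± 0.59). Checkpoint and costimulation genes had 12 of 30 lower and 3 higher (camera adjusted p = 0.00897, adjusted p = 0.661 with an estimated correlation), and 4 higher and 13 lower when adjusted over the list alone; 1 was higher without pBIC10 replicate 1 and 5 without replicate 3. Pdcd1, the inhibitory receptor PD-1, changed by -6.43 ± 0.75 (adjusted p of at most 4.52e-05 for it and Cxcl10).

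Immunoglobulin constant genes went both ways, with 5 of 12 higher and 5 lower (camera adjusted p = 0.527, adjusted p = 0.722 with an estimated correlation), and 7 higher and 5 lower when adjusted over the list alone. Ighm, the constant region of IgM, stood at 7014 ± 643 CPM in pBIC10 and 403 ± 51.5 CPM in pBIC, log2 fold change 4.12 ± 0.24, adjusted p = 2.02e-07. Ighg3, that of IgG3, changed by -6.27 ± 0.89, and Igkc, that of kappa light chains, by -3.45 ± 0.32 (adjusted p of at most 3.47e-04). If each group is 1 clone, these constant genes describe 1 clone against another. Plasma cell and secretory genes, the deleted Prdm1 among them, had 11 of 29 lower and 2 higher (camera adjusted p = 0.00751, adjusted p = 0.662 with an estimated correlation). Adjusted over that list alone, 3 were higher and 15 lower, and the camera adjusted p was at most 0.0175 with 1 library left out. Ebf1, a factor of B cell identity, rose by 3.98 ± 0.49 and Cd55, a complement regulator of resting B cells, by 6.94 ± 0.54 (adjusted p of at most 1.20e-04). They belong to the lists of B cell receptor signalling (7 of 28 higher, 3 lower, camera adjusted p = 0.173, adjusted p = 0.722 with an estimated correlation) and of naive and follicular B cell genes (8 of 22 higher, 2 lower, camera adjusted p = 0.0641, adjusted p = 0.684 with an estimated correlation), which were not called. Adjusted over each list alone, the counts were 9 and 4, and 9 and 3. Both lists were called without pBIC10 replicate 3 (0.0377 and 0.0378) or pBIC replicate 1 (0.0415, 11 higher, and 0.0195) and in females alone (0.0381 and 0.0381). Ranges over alternatives were 0.0195 to 0.123 for the naive and follicular B cell list and 0.0377 to 0.448 for the B cell receptor signalling list. With each lymphoma group summed to 1 library only the first was called, but the spread then comes from YC alone. That call says nothing about stability.

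Ribosomal protein genes were lower by a small amount, 42 of 79 against 1 higher, with a median of -0.57 (camera adjusted p = 5.31e-09, adjusted p = 0.662 with an estimated correlation), and 2 higher and 53 lower when adjusted over the list alone. Without pBIC10 replicate 2, 23 were lower. Rplp1 and Rps26, components of the large and the small subunit, changed by -1.31 ± 0.19 and -1.11 ± 0.17 (adjusted p of at most 3.37e-04). Of the cell cycle genes, 14 of 41 were lower and 4 higher (camera adjusted p = 0.0374, adjusted p = 0.722 with an estimated correlation), and 7 higher and 17 lower when adjusted over the list alone. That call was lost without pBIC10 replicate 1 (adjusted p = 0.0546) or 2 (0.0831, 7 lower) or pBIC replicate 1 (0.0534) or 2 (0.230, 9 lower and 7 higher), with a range over alternatives of 0.00212 to 0.230. Plk1, a kinase of mitosis, changed by -2.11 ± 0.25, while Mcm6, a helicase subunit of DNA replication, rose by 0.99 ± 0.23 (adjusted p of at most 0.00560).

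T cell markers had 12 of 20 lower and 4 higher (camera adjusted p = 0.0251, adjusted p = 0.662 with an estimated correlation), and 4 higher and 12 lower when adjusted over the list alone. Without pBIC10 replicate 2 or 3, 7 were lower. With each lymphoma group summed to 1 library the median of T cell markers was -1.98, as with all libraries. The spread then comes from YC alone, so the loss of the call (camera adjusted p = 0.106, 1 lower and 4 higher, range over alternatives 0.00322 to 0.106) says nothing about stability. Cd8b1 and Cd3g, chains of the CD8 and T cell receptor complexes, changed by -3.89 ± 0.68 and -2.90 ± 0.52, while Il7r, the receptor of IL-7, rose by 4.26 ± 0.88 (adjusted p of at most 0.00368). Among macrophage and monocyte markers, 5 of 20 were lower and 1 higher (camera adjusted p = 0.0451, adjusted p = 0.662 with an estimated correlation), and 1 higher and 5 lower when adjusted over the list alone. That call was lost without pBIC10 replicate 3 (adjusted p = 0.130) or pBIC replicate 1 (0.0800) or 2 (0.167), with sex as a covariate (0.0902) and in females alone (0.115), with a range over alternatives of 0.00512 to 0.167. The lower count ran from 2 without pBIC10 replicate 1 or 3 to 8 without pBIC replicate 1 or 3. Cd68, a lysosomal protein of macrophages, stood at 18.9 ± 5.29 CPM in pBIC10 and 111 ± 9.05 CPM in pBIC, log2 fold change -2.55 ± 0.21, adjusted p = 4.03e-06. NK cell markers had 4 of 12 lower and 0 higher (camera adjusted p = 0.0488, adjusted p = 0.662 with an estimated correlation), and 0 higher and 4 lower when adjusted over the list alone. That call was lost without pBIC10 replicate 2 (0.0582) or 3 (0.0939) or pBIC replicate 1 (0.128, 1 higher) or 2 (0.119), with sex as a covariate (0.0902) and in females alone (0.0862), with a range of 0.0115 to 0.128. Among dendritic cell markers, 2 of 11 were lower and 0 higher (camera adjusted p = 0.0308, adjusted p = 0.662 with an estimated correlation), and 0 higher and 2 lower when adjusted over the list alone. This call was lost without pBIC10 replicate 2 (0.0526) or pBIC replicate 1 (0.0758) or 2 (0.0624), with a range of 0.00517 to 0.209, and 5 were lower without pBIC10 replicate 3.

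Dlk1, a Notch-related surface protein, stood at 711 ± 582 CPM in pBIC10 and 0.0744 ± 0.0867 CPM in pBIC, which had 4 counts in all (log2 fold change 13.11 ± 1.46). Galnt14, an enzyme of O-linked glycosylation, was at least 906-fold higher in pBIC10. Robo1, a guidance receptor, was higher at least 648-fold and Etv1, an ETS transcription factor, at least 545-fold, against 0 counts in pBIC (3 counts over the group set the bound). Slamf8, a SLAM-family receptor, was at least 630.4-fold lower, with 0 counts in pBIC10. Gstt1, a glutathione transferase, stood at 0.830 ± 1.24 CPM in pBIC10 and 381 ± 82.5 CPM in pBIC, log2 fold change -8.77 ± 0.76, adjusted p = 1.14e-05. Serpinb6b, a protease inhibitor, changed by -8.62 ± 0.76, and Cxcr3, the receptor of Cxcl10, by -8.40 ± 1.02 (adjusted p of at most 1.17e-04).

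The comparison of pBIC with YC addressed how lymphoma cells that can make IL-10 differ from normal germinal centre B cells. Genes of the germinal centre state, such as Bcl6, its master regulator, and Neil1, a DNA repair enzyme, were lower in pBIC (adjusted p = 0.238 with an estimated correlation). Of 29 interferon gamma response genes 23 were called higher in pBIC and 2 lower, and of 22 class I presentation genes 13 and 1 (adjusted p = 0.394 and 0.436 with an estimated correlation). On balance this is opposite to pBIC10 against pBIC. Both comparisons use the same pBIC libraries, which by itself favours opposite directions. Of 31 genes of MYC and ribosome biogenesis 27 were called higher, and of 29 genes of respiration 24 (adjusted p = 0.385 and 0.451 with an estimated correlation). Trp53 and Prdm1, the deleted genes, were lower and Ikbkb higher.

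Between pBIC and YC, 9585 of 17718 genes (54.1%) were called, 4682 higher and 4903 lower in pBIC, and 6300 differed at least 2-fold. Groups did not overlap in 54.2% of genes, where chance gives 5.71%. Trp53 changed by -2.60 ± 0.32 (adjusted p = 3.94e-05) and Ikbkb by 1.01 ± 0.17 (adjusted p = 3.50e-04). Prdm1 changed by -1.52 ± 0.45 (adjusted p = 0.0134), and the call was lost without pBIC replicate 3 (adjusted p = 0.0532, range over alternatives 0.00116 to 0.0532). Il10 was not called (0.70 ± 0.41, adjusted p = 0.171).

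Of 29 germinal centre genes, 26 were lower and 0 higher in pBIC, with a median of -2.05 (camera adjusted p = 5.53e-09, adjusted p = 0.238 with an estimated correlation), and 0 higher and 26 lower when adjusted over the list alone. Bcl6 stood at 6.01 ± 3.03 CPM in pBIC and 225 ± 70.8 CPM in YC, log2 fold change -5.23 ± 0.38, adjusted p = 1.02e-06. Neil1 stood at 4.33 ± 1.35 CPM in pBIC and 432 ± 84.4 CPM in YC, log2 fold change -6.64 ± 0.30, adjusted p = 3.60e-08. Basp1, a membrane-linked protein, changed by -5.22 ± 0.36 (adjusted p = 7.12e-07). Gcsam, a signalling protein of the germinal centre, had 1 count in pBIC, and YC exceeded it by a ratio of 4896 (95% counting interval 879 to 193380.0). Nuggc, a GTPase of germinal centres, changed by -10.81 ± 0.96, and Rgs13, a brake on chemokine signals, by -9.93 ± 1.09 (adjusted p of at most 2.64e-05). B cell receptor signalling genes had 17 of 28 lower and 0 higher (camera adjusted p = 1.09e-04, adjusted p = 0.406 with an estimated correlation), and 0 higher and 18 lower when adjusted over the list alone, with 1 higher without pBIC replicate 3. Follicular B cell genes had 17 of 22 lower and 1 higher (camera adjusted p = 5.84e-05, adjusted p = 0.385 with an estimated correlation), and 1 higher and 17 lower when adjusted over the list alone. Ebf1 changed by -6.01 ± 0.52, Cr2, the complement receptor CD21, by -8.47 ± 0.80, and Fcer2a, the IgE receptor CD23, by -9.10 ± 0.33 (adjusted p of at most 1.00e-05).

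Of 29 interferon gamma response genes, 23 were higher and 2 lower in pBIC, with a median of 1.93 (camera adjusted p = 5.84e-05, adjusted p = 0.394 with an estimated correlation), and 23 higher and 2 lower when adjusted over the list alone. Gbp2 stood at 717 ± 479 CPM in pBIC and 18.5 ± 2.96 CPM in YC, log2 fold change 5.27 ± 0.51, adjusted p = 1.10e-05. Gbp3, of the same family, rose by 3.53 ± 0.29. Iigp1, a GTPase that acts on vacuoles of pathogens, rose by 6.47 ± 0.68, while Ciita, the master switch of class II genes, changed by -1.77 ± 0.27 (adjusted p of at most 1.71e-04 for the 3). Of 22 class I presentation genes, 13 were higher and 1 lower (camera adjusted p = 0.00290, adjusted p = 0.436 with an estimated correlation), and 13 higher and 1 lower when adjusted over the list alone, with 2 lower without pBIC replicate 3 or YC replicate 1. Erap1, which trims peptides, rose by 1.54 ± 0.16, Tapbp by 1.08 ± 0.14 and Psme1, a proteasome activator, by 1.31 ± 0.18, and H2-M3, a class I molecule for bacterial peptides, changed by -0.81 ± 0.17 (adjusted p of at most 0.00165 for the 4).

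NF-kB targets had 24 of 43 lower and 4 higher (camera adjusted p = 0.00164, adjusted p = 0.385 with an estimated correlation), and 4 higher and 25 lower when adjusted over the list alone, with 2 higher without YC replicate 1 or 3. Bcl2l1, which encodes the survival protein BCL-XL, changed by -2.70 ± 0.19, and Ccl22, a chemokine that draws T cells, by -5.54 ± 0.49 (adjusted p of at most 3.55e-06). Bcl2, the founding member of that survival family, stood at 179.7 ± 67.0 CPM in pBIC and 38.3 ± 5.61 CPM in YC, log2 fold change 2.23 ± 0.24, adjusted p = 1.07e-05. The list of activated B cell-like lymphoma genes, Bcl2 among them, had 7 of 26 higher and 6 lower and was not called (camera adjusted p = 0.548, adjusted p = 0.866 with an estimated correlation). In pBIC10 against pBIC it had 9 lower and 1 higher (camera adjusted p = 0.0257, adjusted p = 0.662 with an estimated correlation). That call was lost without pBIC replicate 1 (camera adjusted p = 0.0898).

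Of 31 genes of MYC and ribosome biogenesis, 27 were higher and 0 lower (camera adjusted p = 8.10e-08, adjusted p = 0.385 with an estimated correlation), and 27 higher and 0 lower when adjusted over the list alone. Wdr12, a ribosome assembly factor, rose by 2.11 ± 0.15, and the nucleolar proteins Npm1 and Ncl by 1.95 ± 0.19 and 1.31 ± 0.15. Ribosomal protein genes had 71 of 79 higher and 0 lower (camera adjusted p = 4.87e-14, adjusted p = 0.385 with an estimated correlation), and 73 higher and 0 lower when adjusted over the list alone, with Rplp0, of the ribosomal stalk, up by 1.42 ± 0.14. Respiratory chain genes had 24 of 29 higher and 0 lower (camera adjusted p = 3.06e-05, adjusted p = 0.451 with an estimated correlation), and 24 higher and 0 lower when adjusted over the list alone, with Cox4i1, a subunit of complex IV, up by 1.45 ± 0.22 (adjusted p of at most 1.46e-04 for the 5). Glycolysis and hypoxia genes had 16 of 26 higher and 4 lower (camera adjusted p = 0.0115, adjusted p = 0.394 with an estimated correlation), and 16 higher and 5 lower when adjusted over the list alone. Pdk1, which limits entry of pyruvate into mitochondria, rose by 2.41 ± 0.17, and Pkm, pyruvate kinase, by 1.31 ± 0.17 (adjusted p of at most 5.14e-05).

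Histone genes that are expressed in S phase and whose transcripts lack poly(A) tails had 58 of 60 lower and 0 higher in pBIC (camera adjusted p = 1.48e-14, adjusted p = 0.385 with an estimated correlation), and 0 higher and 59 lower when adjusted over the list alone, with H2ac23 at -1.97 ± 0.24. Mitochondrial rRNA and tRNA had 18 of 21 lower and 0 higher (camera adjusted p = 1.43e-05, adjusted p = 0.385 with an estimated correlation), and 0 higher and 18 lower when adjusted over the list alone, with mt-Rnr1 and mt-Rnr2, the ribosomal RNAs, at -2.51 ± 0.19 and -1.91 ± 0.20. Immediate early and heat shock genes, which handling can raise, had 15 of 18 lower and 0 higher (camera adjusted p = 1.09e-04, adjusted p = 0.385 with an estimated correlation), and 1 higher and 16 lower when adjusted over the list alone, with 1 higher without pBIC replicate 3. Among them the AP-1 factors Junb and Jund changed by -2.47 ± 0.27 and -2.64 ± 0.30 (adjusted p of at most 2.60e-05 for the 5). The histone and mitochondrial lists were included as signs of RNA quality or poly(A) selection. Mitochondrial rRNA and tRNA held 1.98% of counts in YC, 0.497% in pBIC and 0.397% in pBIC10, and histone genes 0.111, 0.0231 and 0.0332%. In both comparisons with YC, a technical difference of the YC libraries cannot be told apart from a difference between the cells.

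Markers of T cells, macrophages and NK cells were lower in pBIC than in YC. Dendritic cell markers (2 higher and 3 lower of 11, 0 higher and 2 lower when adjusted over the list alone) and erythroid markers (0 of 13 called by edgeR) were not called as lists. Higher dendritic cell markers fell to 0 without pBIC replicate 3 or YC replicate 2 or 3 and to 1 without any other library, lower ones fell to 1 without YC replicate 1, 2 or 4, and 6 were lower in females alone. Without YC replicate 4, 2 erythroid markers were higher, and without pBIC replicate 3, 1 was lower. T cell markers had 19 of 20 lower and 0 higher (camera adjusted p = 4.06e-07, adjusted p = 0.385 with an estimated correlation), macrophage markers 16 lower and 1 higher of 20 (camera adjusted p = 1.09e-04, adjusted p = 0.385 with an estimated correlation) and NK cell markers 10 lower and 0 higher of 12 (camera adjusted p = 2.85e-04, adjusted p = 0.385 with an estimated correlation). Adjusted over the list alone, these counts were 19 and 0, 16 and 1, and 10 and 0. Lck, a kinase of T cells, stood at 14.4 ± 9.91 CPM in pBIC and 187 ± 16.4 CPM in YC, log2 fold change -3.70 ± 0.40, adjusted p = 2.12e-05. Trbc2, a T cell receptor chain, changed by -3.71 ± 0.44. Csf1r, the receptor of macrophage growth factor, changed by -3.51 ± 0.32, Apoe, a lipid carrier of macrophages, by -3.15 ± 0.48, and Gzma, a protease of NK cells, by -5.20 ± 0.66, while Cd68 rose by 1.86 ± 0.19 (adjusted p of at most 2.26e-04 for the 5).

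Among the largest changes, Onecut2, a homeobox factor of liver and nerve cells, stood at 306 ± 81.7 CPM in pBIC and 0.685 ± 0.657 CPM in YC, log2 fold change 8.76 ± 0.56, adjusted p = 7.73e-07. Ebf3, a relative of Ebf1, rose by 7.95 ± 0.62 (adjusted p = 2.84e-06). Fzd6, a Wnt receptor, had 3 counts in YC and pBIC exceeded it by a ratio of 607 (95% counting interval 208 to 2943). Plk2, a kinase that p53 induces, had 3 counts in pBIC and YC exceeded it by 1573 (95% counting interval 538 to 7628). The p53 targets had 12 of 26 lower and 5 higher in pBIC and were not called as a list (camera adjusted p = 0.0921, adjusted p = 0.385 with an estimated correlation). In pBIC10, where Trp53 is deleted as well, 8 were higher and 6 lower than in YC (camera adjusted p = 0.771, adjusted p = 0.814 with an estimated correlation). The fall of Plk2 therefore does not stand for these targets as a set. Emid1, a matrix protein, had 3 counts in pBIC and YC exceeded it by 1507 (95% counting interval 516 to 7309).

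The comparison of pBIC10 with YC addressed how lymphoma cells deficient in IL-10 differ from normal germinal centre B cells. Of 29 germinal centre genes, 25 were called lower in pBIC10, Neil1 among them, and 1 higher, where in pBIC 26 were lower (adjusted p = 0.198 and 0.238 with an estimated correlation). In pBIC10 against pBIC, 12 of these genes were higher and 5 lower, with a median of 0.40. That list was not called there (camera adjusted p = 0.288, adjusted p = 0.722 with an estimated correlation). Of 43 tested NF-kB targets, 35 were called lower although Ikbkb was raised (adjusted p = 0.198 with an estimated correlation), and among them were the survival genes Bcl2l1 and Bcl2a1b. Of 18 class II presentation genes, 12 were called lower, H2-Ab1 among them, and 3 higher (adjusted p = 0.354 with an estimated correlation). Of 29 interferon gamma response genes, 15 were called below YC, whereas in pBIC 23 were called above it (adjusted p = 0.528 and 0.394 with an estimated correlation).

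Between pBIC10 and YC, 9158 of 17718 genes (51.7%) were called, 4394 higher and 4764 lower in pBIC10, and 6257 differed at least 2-fold. Groups did not overlap in 61.0% of genes, where chance gives 5.71%. Trp53 changed by -2.10 ± 0.31 (adjusted p = 1.48e-04), Prdm1 by -5.02 ± 0.56 (adjusted p = 2.22e-05) and Ikbkb by 1.47 ± 0.17 (adjusted p = 2.25e-05). Il10 changed by -1.18 ± 0.44 (adjusted p = 0.0371), a call that was lost without pBIC10 replicate 1 (adjusted p = 0.112) or 2 (0.143), without YC replicate 2 (0.0687), 3 (0.0614) or 4 (0.1001). Limma-voom (0.0547) and scaling by library size alone (0.0540) ended it too, and over alternatives its adjusted p ran from 0.0142 to 0.143.

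Of 43 NF-kB targets, 35 were lower and 1 higher in pBIC10, with a median of -1.66 (camera adjusted p = 1.80e-09, adjusted p = 0.198 with an estimated correlation), and 1 higher and 36 lower when adjusted over the list alone. Bcl2l1 stood at 6.11 ± 0.374 CPM in pBIC10 and 46.8 ± 2.38 CPM in YC, log2 fold change -2.93 ± 0.19, adjusted p = 4.00e-07. Cd83 stood at 21.1 ± 5.46 CPM in pBIC10 and 319 ± 42.6 CPM in YC, log2 fold change -3.92 ± 0.26, adjusted p = 4.40e-07. Bcl2a1b, another BCL2-family survival gene, changed by -5.73 ± 0.43 and Ccl22 by -5.64 ± 0.49, and the higher member was Birc3 (1.07 ± 0.17, adjusted p of at most 1.86e-04 for the 3). Bcl2 rose by 1.502 ± 0.23 (adjusted p = 1.70e-04). Of 29 germinal centre genes, 25 were lower and 1 higher (camera adjusted p = 6.11e-08, adjusted p = 0.198 with an estimated correlation), and 1 higher and 25 lower when adjusted over the list alone. Neil1 stood at 23.1 ± 5.52 CPM in pBIC10 and 432 ± 84.4 CPM in YC, log2 fold change -4.23 ± 0.27, adjusted p = 2.70e-07. Gcsam and Mef2b, a partner factor of Bcl6, each had 3 counts in pBIC10, and YC exceeded them by ratios of 1588 (95% counting interval 543 to 7699.9) and 187 (95% counting interval 64.0 to 906). The higher member was Ung, which removes uracil from DNA (0.61 ± 0.23, adjusted p = 0.0428), and its call was lost without pBIC10 replicate 3 (adjusted p = 0.233) or YC replicate 1 (0.0937), 2 (0.121) or 4 (0.0920), or in females alone (0.136), with a range over alternatives of 0.0103 to 0.410.

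Of 18 class II presentation genes, 12 were lower and 3 higher (camera adjusted p = 0.00159, adjusted p = 0.354 with an estimated correlation), and 3 higher and 12 lower when adjusted over the list alone. H2-Ab1, a class II chain, stood at 685 ± 145 CPM in pBIC10 and 3149 ± 328 CPM in YC, log2 fold change -2.20 ± 0.18, adjusted p = 1.39e-06. H2-Aa changed by -1.56 ± 0.15. Lgmn, a lysosomal protease, rose by 1.04 ± 0.27 (adjusted p of at most 0.00653). Of 29 interferon gamma response genes, 15 were lower and 2 higher (camera adjusted p = 0.00608, adjusted p = 0.528 with an estimated correlation), and 2 higher and 16 lower when adjusted over the list alone, with 1 higher without any 1 of the pBIC10 libraries or YC replicate 2 or 3. Ciita changed by -2.36 ± 0.28 and Icam1 by -1.79 ± 0.17, while Gbp3 rose by 2.07 ± 0.28 (adjusted p of at most 7.39e-05). Of 22 class I presentation genes, 11 were lower and 2 higher (camera adjusted p = 0.0197, adjusted p = 0.536 with an estimated correlation), and 2 higher and 11 lower when adjusted over the list alone, with 1 higher without pBIC10 replicate 1 or YC replicate 2, and with Tap1 at -1.26 ± 0.20 (adjusted p = 1.65e-04). Of 18 regulatory B cell genes, 13 were lower and 2 higher (camera adjusted p = 0.00159, adjusted p = 0.326 with an estimated correlation), and 3 higher and 13 lower when adjusted over the list alone, with 1 higher without YC replicate 1 or 2. Havcr1, which encodes the regulatory B cell marker TIM-1, changed by -5.79 ± 0.33, and Nfil3, a factor that Il10-making cells express, by -4.74 ± 0.43 (adjusted p of at most 4.68e-06).

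Of 31 genes of MYC and ribosome biogenesis, 24 were higher and 1 lower in pBIC10 (camera adjusted p = 1.44e-07, adjusted p = 0.354 with an estimated correlation), and 25 higher and 1 lower when adjusted over the list alone. Wdr12 rose by 2.28 ± 0.15, Noc2l, another assembly factor, by 1.64 ± 0.15 and Ncl by 1.42 ± 0.15, while Odc1, the first enzyme of polyamine synthesis, changed by -1.63 ± 0.35 (adjusted p of at most 0.00229). Immunoglobulin constant genes had 8 of 12 lower and 1 higher (camera adjusted p = 0.00627, adjusted p = 0.354 with an estimated correlation), and 1 higher and 9 lower when adjusted over the list alone, with 5 lower without pBIC10 replicate 1. Igkc changed by -5.13 ± 0.34 and Iglc2, a lambda constant region, rose by 2.12 ± 0.18 (adjusted p of at most 1.95e-06).

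Histone genes had 55 of 60 lower and 0 higher (camera adjusted p = 8.51e-12, adjusted p = 0.354 with an estimated correlation), and 0 higher and 57 lower when adjusted over the list alone, with H2ac15 at -2.63 ± 0.35. Mitochondrial rRNA and tRNA had 10 of 21 lower and 0 higher (camera adjusted p = 0.00104, adjusted p = 0.354 with an estimated correlation), and 0 higher and 10 lower when adjusted over the list alone, with mt-Rnr1 at -3.68 ± 0.21. Immediate early and heat shock genes had 12 of 18 lower and 1 higher (camera adjusted p = 0.00608, adjusted p = 0.354 with an estimated correlation), and 1 higher and 12 lower when adjusted over the list alone. Hspa1b, the stress-induced form of HSP70, changed by -6.44 ± 0.83, and the higher member was Hsp90aa1, a chaperone (1.34 ± 0.21, adjusted p of at most 1.65e-04 for these 4). T cell markers had 17 of 20 lower (camera adjusted p = 2.61e-08, adjusted p = 0.326 with an estimated correlation), macrophage markers 19 of 20 (camera adjusted p = 3.10e-07, adjusted p = 0.326 with an estimated correlation) and NK cell markers 12 of 12 (camera adjusted p = 1.49e-06, adjusted p = 0.326 with an estimated correlation), with 0 higher in each, and the counts were 17, 19 and 12 when adjusted over the list alone. Trbc2 changed by -5.80 ± 0.51 and Csf1r by -4.09 ± 0.33 (adjusted p of at most 3.42e-06).

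Among the largest changes in pBIC10 against YC, Dlk1 stood at 711 ± 582 CPM in pBIC10 and 0.717 ± 0.498 CPM in YC, log2 fold change 9.93 ± 1.06, adjusted p = 2.06e-05. Adgrd1, an adhesion receptor, stood at 124 ± 27.2 CPM in pBIC10 and 0.142 ± 0.164 CPM in YC, log2 fold change 9.64 ± 0.51, adjusted p = 1.46e-07. Clmn, an actin-binding protein, rose by 9.17 ± 0.61 (adjusted p = 9.34e-07). Necab2, a calcium-binding protein of nerve cells, had 3 counts in YC and pBIC10 exceeded it by a ratio of 2137 (95% counting interval 731 to 10365). Jchain, which joins IgM and IgA units, stood at 5.87 ± 2.97 CPM in pBIC10 and 1509.5 ± 575 CPM in YC, log2 fold change -8.00 ± 0.89, adjusted p = 2.88e-05. Grm6, a glutamate receptor, changed by -8.79 ± 0.89 (adjusted p = 1.41e-05).

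Camera with its preset correlation called 20 of 37 gene lists in pBIC10 against pBIC (0 higher, 20 lower), 19 in pBIC against YC (6 higher, 13 lower) and 29 in pBIC10 against YC (3 higher, 26 lower). With a correlation estimated from these libraries camera called 0, 0 and 0 lists, so no list call holds with an estimated correlation, and 3, 1 and 4 lists had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move 1 way and does not compare them with other genes, called 18, 28 and 31. The list median, mean and test differed in sign for dendritic cell, unfolded protein, memory B cell and erythroid lists and for the checkpoint list in pBIC against YC, and for glycolysis and B-1 cell lists in pBIC10 against YC, and none of these was called.

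Of the genes called against YC in both lymphoma groups, 5901 went the same way, 2638 higher and 3263 lower, and 435 went opposite ways. Lists drawn independently would share 1161 higher and 1318 lower genes and give 2475 opposite ones. Both comparisons use the same 4 YC libraries. In 20 simulations with unchanged lymphoma groups against shared controls, at most 0 genes were shared in direction (edgeR). Few calls can arise where no gene changes, so this count was nearly fixed in advance. The correlation of log2 fold changes across genes had a median of 0.434 in the simulations, against 0.648 observed. Correlation leaves out the size of the changes, and their covariance had a median of 0.0695 in the simulations, against 2.48 observed. With separate pairs of YC libraries for each group, 4313 to 4461 genes went the same way and 251 to 293 opposite, with correlations of 0.589 to 0.610. Of the 2674 genes lower in pBIC10 than in pBIC, 1002 differed from YC in pBIC alone, 723 in pBIC10 alone, 547 in both the same way, 205 in opposite ways and 197 in neither. Of the 2766 higher genes, these counts were 808, 896, 680, 230 and 152.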

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

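Of the tests below, those on variable segments, other cells, mislabelled sex and other groupings of the libraries were chosen after the result was seen, as were the controls for X-linked genes.

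The first results lie apart in 1 YC library. In 112 sets of 4 YC libraries, the gap of the highest or lowest library to its neighbour, divided by the range, passed 0.829 in 9, and chance gives about 1 in 20 (5.60). The ratios were 0.961 for Batf (45.2, 70.3, 45.5 and 46.2 CPM), 0.860 for Irf1 (126, 129, 100.45 and 125 CPM), 0.867 for Pdcd1 (3.71, 1.47, 1.13 and 1.21 CPM) and 0.928 for Neil1 (395, 383, 558 and 390.2 CPM). Cr2 had 0.877 (178, 175, 200.5 and 175 CPM) and Pdk1 0.846 (28.2, 31.9, 31.4 and 31.3 CPM). Fzd6 (0.871), Ebf3 (0.896) and Necab2 (0.871) were near the level of single counts in YC.

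Of the genes named in the text, 17 differed from YC in opposite directions in pBIC and pBIC10, and were also called in pBIC10 against pBIC in edgeR. Many of them were named for their change in pBIC10 against pBIC, so that call was nearly fixed in advance and is no separate support. Over all 17718 tested genes, 205 were higher in pBIC and lower in pBIC10 than YC by the same rule, and 230 the reverse. Genes above YC in pBIC and below it in pBIC10 were Slamf8 (fitted log2 fold change between the lymphoma groups -12.16), Gstt1 (-8.77), Serpinb6b (-8.62), Pdcd1 (-6.43), Lag3 (-5.29), Cxcl10 (-5.14), Gbp8 (-4.27), Gbp4 (-3.95), Batf (-3.71), Cd68 (-2.55), Tap1 (-1.74) and Irf1 (-1.63). Genes below YC in pBIC and above it in pBIC10 were Galnt14 (12.65), Robo1 (12.17), Etv1 (11.92), Cd55 (6.94) and Il12a (5.82). For Slamf8, Galnt14, Robo1 and Etv1 a lymphoma group had 0 counts, so the fitted value depends on the prior count and is no bound.

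All 3 libraries of each lymphoma group share a leading heavy chain segment, Ighv7-3 in pBIC10 and Ighv8-11 in pBIC. Independent lymphomas drawing segments at the YC shares would give 1 segment in 3 draws with a chance of 0.000311. RNA passed in part between libraries would leave a second heavy chain family, which held at most 9.84%. Passed RNA that replaced nearly all of a library's own would also leave little of one, so this value cannot exclude it. The leading light chain segment was also shared, at no less than 72.7%. A shared lambda leader alone does not mark a lineage, since Iglv1 led in all 4 YC libraries with 75.3 to 81.2% of lambda counts. The segments themselves differed from YC, where Iglv2 held 10.5 to 13.9% of lambda counts and Igkv6-17 0.957 to 2.51% of kappa counts. Taken with the heavy chain segments, 1 B cell lineage behind each group is a candidate explanation. The pBIC10 libraries come from mice of both sexes, in which such a lineage would have to have been present. They held little of the transcripts particular to either sex. Xist was at 5.05 and 3.98% of female YC in the female libraries, and Y-linked genes at 8.20% of male YC in the male library. The sex labels therefore cannot decide whether these libraries share a lineage. Selection of the same receptor in separate lymphomas was not tested and stays open.

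Interferon gamma response genes were lower in pBIC10 than in pBIC, with a median of -2.36 (camera adjusted p = 5.43e-14, adjusted p = 0.541 with an estimated correlation). Removing a trend on GC content and transcript length (29 of 29 genes matched) left -2.61, which argues against such a bias, and 52 markers of T cells, NK cells and macrophages, which a sort on B220 should remove, had a median of -3.16 (quartiles -3.98 to -1.99) in pBIC against YC where the list had 1.93 (0.85 to 3.54), which argues against RNA of those cells as its whole source. In pBIC10 against pBIC the median of the markers fell too (-1.50, or -1.15 with the 4 that had 0 counts in pBIC10 at their bound). Of the 4 that reach 5 CPM in all groups, Lck (1.61, adjusted p = 0.00732) and Cd2 (2.08, adjusted p = 0.00242) rose, Cd68 fell (-2.55, adjusted p = 4.03e-06) and Apoe was not called (0.43, adjusted p = 0.514). That level was required in pBIC10 too, so markers that fell below it there are left out of these 4. Among all 20 T cell markers, 12 were lower and 4 higher in pBIC10, so Lck and Cd2 do not show more T cell RNA there. Only 1 of the markers (Gzmb) is in another list. Library batch cannot be told apart from group, because 0 pBIC10 libraries are in the other batch, and fewer cells that make interferon gamma around pBIC10 cells stays open and untested. Ifng itself, chosen after its values were seen, had means of 0.436, 1.02 and 4.34 CPM in pBIC10, pBIC and YC, and was not called in pBIC10 against pBIC (-1.21, adjusted p = 0.268).

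Xist, which silences the second X chromosome of females, stood at 40.5 and 31.9 CPM in the female pBIC10 libraries against 716 to 944 CPM in female YC, and 4 Y-linked genes at 15.1 CPM in the male pBIC10 library against 184 CPM in the male YC library. Exchanged sexes are argued against, since the counterpart signal reached at most 0.445% of YC. Both X chromosomes being active may raise X-linked genes. In female pBIC10 against YC 642 of them lay 0.328 (0.238 to 0.388) above 17327 autosomal genes. However, female pBIC libraries, which keep Xist, gave 0.240, and the male pair gave 0.308 (0.225 to 0.369). That pair is a control only if the male pBIC10 library does not share a lineage with the female pBIC10 libraries. With a shared lineage, active X chromosomes could give a similar shift in both sexes, so the male pair cannot decide. Loss of the inactive X would lower Kdm6a, Ddx3x, Kdm5c and Eif2s3x, whose median lay -0.0890 from other X-linked genes with members on both sides. Neither can be told apart from other causes with these values, and no biological explanation was tested further.

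Other groupings of the same libraries were fitted with edgeR for the numbers of genes changed. For pBIC10 against pBIC the real grouping gave 5440 genes and the highest other 2, with 1 of 10 groupings as large, too few for a share under 0.05. For pBIC against YC 1 of 35 was as large (9585 genes, highest other 0), and for pBIC10 against YC 1 of 35 (9158 genes, highest other 0), so chance in the grouping is excluded for these only if the libraries of a group are independent, which libraries of 1 lineage would not be.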

How the results depend on the processing

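Among these alternatives, summing each lymphoma group to 1 library was chosen after the result was seen. No paired analysis was possible because the libraries come from separate mice with no pairing in the labels.

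The number of genes changed between pBIC10 and pBIC (5440, 2766 higher and 2674 lower) moved by more than 1.5 times under 3 alternatives. An adjusted p under 0.01 gave 3145 (1656 higher, 1489 lower), a minimum fold of 1.5 gave 2754 (1543 and 1211), both by their stricter threshold, and summing each lymphoma group to 1 library gave 2925 (1576 and 1349). Summing leaves 1 library in each lymphoma group, so the spread comes from the YC libraries alone and the lone libraries are assumed to vary like them. A minimum fold of 1.5 gave 5954 genes (2506 higher) in pBIC against YC and 5872 (2525 higher) in pBIC10 against YC. Other alternatives stayed within 1.5 times. In pBIC10 against pBIC these gave 3810 genes with a fit of the 2 groups, 4586 with females alone, 5015 with sex as a covariate, 5621 with limma-voom and 6042 with DESeq2. Leaving out 1 library gave 3884 to 6052, 8331 to 9875 and 7969 to 8324 genes in the 3 comparisons.

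Gene lists depended on the correlation assumed. An estimated correlation gave 0 called lists in pBIC10 against pBIC, 0 in pBIC against YC and 0 in pBIC10 against YC with camera (3, 1 and 4 at an unadjusted p under 0.05), against 20, 19 and 29 with the preset one and 18, 28 and 31 with fry. The estimate from 10 libraries has few degrees of freedom. In pBIC10 against pBIC, 12 lists were called without pBIC replicate 1, 13 without replicate 2 and 23 without replicate 3. With each lymphoma group summed, calls were lost in pBIC10 against pBIC for T cell markers (camera adjusted p = 0.106, median -1.98 against -1.98), the IL-10 receptor and STAT3 pathway (0.0549, -0.38 against -0.39) and dendritic cell markers (0.209, -1.10 against -1.38). In pBIC against YC they were lost for the plasma cell and secretory programme (0.0561, -0.63 against -0.67) and the immunoglobulin constant region (0.0508, -2.99 against -3.04). Calls were gained for naive and follicular B cell genes in pBIC10 against pBIC and erythroid markers in pBIC10 against YC. With the spread taken from YC alone, these gains say as little about stability as the losses.

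Named genes kept their direction under all alternatives run, with 0 reversed. Lck, Cd2, Apoe and Ifng in pBIC10 against pBIC were not run under these alternatives. Of 957, 986 and 858 values in the 3 comparisons, 923, 983 and 836 stayed on their side of the threshold, 32, 3 and 22 lost the call and 2, 0 and 0 gained it. These losses and gains belong to 10, 2 and 4 genes. With each lymphoma group summed, Fos (3.19, adjusted p = 0.291, against 3.23 with all libraries), Ighg3 (-6.26, 0.295, against -6.27), Igkc (-3.42, 0.0551, against -3.45), Cd8b1 (-3.84, 0.0586, against -3.89), Cd3g (-2.87, 0.0602, against -2.90), Mcm6 (1.03, 0.0597, against 0.99), Ifngr1 (0.61, 0.102, against 0.58) and Birc3 (0.52, 0.169, against 0.52) were no longer called in pBIC10 against pBIC. Hspa1b (-6.41, 0.0717, against -6.44) and Il10 (-1.09, 0.0744, against -1.18) were no longer called in pBIC10 against YC. These fold changes moved little. With the spread taken from YC alone, calls lost or gained say nothing about the stability of these genes or of the lists above. With a minimum fold of 1.5, calls were lost for Mcm6 (0.0787), Ifngr1 (0.586) and Birc3 (0.722) in pBIC10 against pBIC, H2-M3 (0.0854) in pBIC against YC, and Lgmn (0.0544), Il10 (0.107) and Ung (0.410) in pBIC10 against YC.

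The overlap of the lymphoma groups against YC was 3957 genes in the same direction at an adjusted p under 0.01. The first 2 components held 91.2% of variance with 2000 genes and 93.5% without immunoglobulin genes. Genes of low level were found less often in simulated data for pBIC10 against pBIC. Of genes changed 4-fold, 5 of 38 under 5 CPM and 50 of 62 at 5 CPM or more were found. Depth was not varied, so its part cannot be told apart from that of group size or spread. The simulation changed far fewer genes than were called in the data, which makes the adjusted p harder to pass. These shares therefore do not give the power in the data.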
